A study of Mus musculus with 2 samples.

How the data were processed

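RNA of mouse back skin keratinocytes was measured on 2 Illumina expression bead arrays, 1 for conditional Med1 knockout mice (Med1cKO) and 1 for littermate controls without Cre (CON). According to the series' design text, keratinocytes of 3 mice per genotype were combined and sorted by flow cytometry, and the integrin alpha6 positive, CD34 negative fraction was collected. Other protocol fields of the same samples describe RNA taken from whole skin of each mouse. The sorted, combined origin was used here because the sample source, the cell type label and the design text all give it. Groups were taken from the sample titles.

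The deposited probe intensity values of both arrays are linear, not normalized between arrays, and not background-subtracted, per the file headers and the values themselves. GenomeStudio 2011.1 is named in the submitters' processing notes, and the RNA was biotin-labelled and detected with Cy3-streptavidin per the labels' protocols. The detection p-value that the deposited file gives beside each probe intensity, per the file headers, compares the probe with negative control beads of its own array. Bead numbers and bead-level errors were not used here. A second set of intensity values, normalized by the authors, was used as an alternative. Their medians were 198 for CON and 199 for Med1cKO, and both arrays shared a 75th percentile of 586. These values are on a linear scale, uncentred, and run the same way as the non-normalized values of their own array (rank correlation 1 for both). The values show quantile normalization without background subtraction, and the method is not given in the sources used here. Their lowest (130.8) and highest (44357) values exceed those of both non-normalized arrays, so their common distribution is not the mean of these 2 arrays, and whether other arrays entered the normalization is unknown.

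Intensities were background-corrected, normalized and log2-transformed with the neqc function of limma 3.58.1 in R 4.3.3. neqc fits a normal plus exponential model, with the background inferred from the detection p-values, adds an offset of 16, and applies quantile normalization. The inferred background had a mean of 168.0 and an SD of 21.9 intensity units on the CON array, and a mean of 163.0 and an SD of 17.0 on the Med1cKO array. Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

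Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, none had several, and 1719 had none (654 of these were detected) and were left out of gene counts. Symbols were looked up by Entrez ID in a RefSeq table of assembly GRCm38.p6. This matched 23962 probes without changing a symbol, and 16 probes kept the array's symbol. No genome build is named for the array annotation, so no coordinates are given. The probes covered 16593 genes, 4777 of them with several probes. Each gene was represented by its probe with the highest mean normalized level.

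A gene was called detected at a detection p below 0.01. The 7955 genes detected on at least 1 array were compared by the log2 ratio, Med1cKO minus CON. Where only 1 array detected a gene, the ratio is a bound: the dim value was raised to the lowest normalized value of any detected probe on that array (log2 6.41 for CON, 6.20 for Med1cKO), and the difference is written as at least N-fold. It is a lower bound only on the background-corrected scale. Deposited intensities hold the background on both arrays, so their ratios are smaller. No fold is given where this bound is below 1. For 11 genes of this kind another, dimmer probe was detected on the other array too, and among the named genes this holds for Egfl7. A further 3 genes were left out although a dimmer probe was detected.

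With 1 array per group there is no replicate error, no test and no p-value for any difference, and the number of arrays limits the precision. Differences are described by 3 fixed rules instead. A gene was counted when it differed at least 2-fold. A ratio was set beside the robust SD (scaled median absolute deviation) of the log2 ratios of genes of similar level, in 10 bins, which is a spread between genes and not a replicate error. A gene list was described by the median measured log2 ratio of its detected members and by its percentile among 10000 random lists of the same size matched on level in 20 bins. A list is said to stand apart when that percentile lies in the highest or lowest 2.5%. Lists with fewer than 4 detected members have values per gene only.

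The 32 gene lists, the rules and the alternatives were fixed before the data were examined. The rule for named genes took Med1, Krt14, Itga6 and Cd34, the 12 highest and 12 lowest ratios among genes detected on both arrays, the 5 brightest genes per direction among those detected on 1 array with a bound of at least 2-fold, and up to 4 detected members of each list with the largest absolute ratios. Clone names were left out. Genes outside this rule are named as chosen after their values were seen.

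The steps were tested on simulated data for the comparison of CON with Med1cKO. Over 8845 simulated genes with 200 seeded changes, 100% of the genes seeded 4-fold or 8-fold higher were called, as were 98% of those seeded 4-fold lower and 100% of those seeded 8-fold lower. Of the unchanged genes, 0.625% were called. Of 1000 unchanged lists of 15 genes, 6.6% fell in the outer 5%, and 98 of 100 lists shifted by 0.5 stood apart. These shares rest on simulated log2 noise with an SD of 0.25, added to each array separately, and do not include variation between mice. The ratios of the real arrays had a robust SD of 0.97 in the dimmest level bin, so the shares need not hold for these data. Seeded genes were drawn only from those detected in CON and well above background there, so the shares called do not cover dimmer genes.

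The alternatives were no background correction, a median shift or cyclic loess in place of quantile normalization, offsets of 50 and 1, a detection p below 0.05, detection on both arrays, no detection filter, the mean over detected probes, the authors' normalized values, and thresholds of 1.5-fold and 3-fold. For lists, genes at their bound and the mean in place of the median were tried as well. A count without the genes of the other-cell-type lists was added after seeing the data.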

Results

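Gene expression was measured in sorted mouse keratinocytes in which Med1, a subunit of the Mediator coactivator complex that links transcription factors to RNA polymerase II, was removed by Cre recombinase under the keratin 14 promoter. Keratin 14 marks basal cells of the epidermis and hair follicle outer layer. The sorted cells carried integrin alpha6, a basal cell adhesion receptor, and lacked CD34, a marker of follicle bulge stem cells in the mouse. Each genotype was represented by 1 array, hybridized with RNA of 1 pool from 3 mice. The 2 arrays had similar brightness, with median intensities of 197.6 (CON) and 191.17 (Med1cKO) and highest intensities of 44136 and 43366. Of 25697 probes, 10476 (40.8%) were detected on the CON array and 10960 (42.7%) on the Med1cKO array. By gene, 528 were detected on the Med1cKO array only and 245 on the CON array only. A probe had to be brighter to be detected on CON. Cd3e at an intensity of 238.7 was not detected there, while Gli3 at 224.6 was detected on Med1cKO. Detection in the Med1cKO pool only can therefore partly reflect this lower cut. There were no replicates, so every difference below compares 2 pools and has no replicate error.

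The comparison asks how the transcripts of this epidermal population differ when Med1 is missing, and the series title names epidermal fate and regeneration after injury as its subjects. The brightest Med1 probe was 1.996-fold lower in the Med1cKO pool, with an intensity of 794 in CON and 452 in Med1cKO (log2 ratio -0.997; genes of similar level had a robust SD of 0.40), or 1.65-fold without background correction. A second probe was 1.77-fold lower (log2 ratio -0.82). The third was detected in CON only, at least 1.82-fold lower in Med1cKO, and the fourth was detected on neither array. The deleted exons are not given in the sources used here, so these probes cannot check the deletion. Krt14, whose promoter drives Cre, had log2 ratio 0.09, Itga6, which encodes integrin alpha6, -0.13, and Cd34 -0.31.

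More genes were higher than lower in the Med1cKO pool. Among 7955 detected genes, 314 (3.95%) were at least 2-fold higher and 144 (1.81%) at least 2-fold lower. Of these, 252 and 124 were detected on both arrays. At least 4-fold differences were found for 57 higher and 15 lower genes. The log2 levels of the 2 arrays correlated across genes with Pearson's r = 0.958, where genes are not independent replicates, and the median log2 ratio was -0.04. The robust SD of the ratios was 0.97 in the dimmest of 10 level bins and 0.23 in the brightest. Without background correction the counts were 145 and 43, and with the authors' normalized values 163 and 46. Single folds depend on this step too. All folds below, including those written as at least N-fold, are after background correction, and the folds of all 72 genes named by the fixed rule and at least 2-fold different were smaller without it, 38 of them by over 1.5 times (up to 2.76 times) and 17 to below 2-fold, with none changing sign. In 1778 genes with several probes detected on both arrays, the ratios of the 2 brightest probes had r = 0.714 across genes. For 51 of 53 such genes with a 2-fold difference, the second probe pointed the same way, and for 31 it also reached 2-fold.

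**Figure D1:**
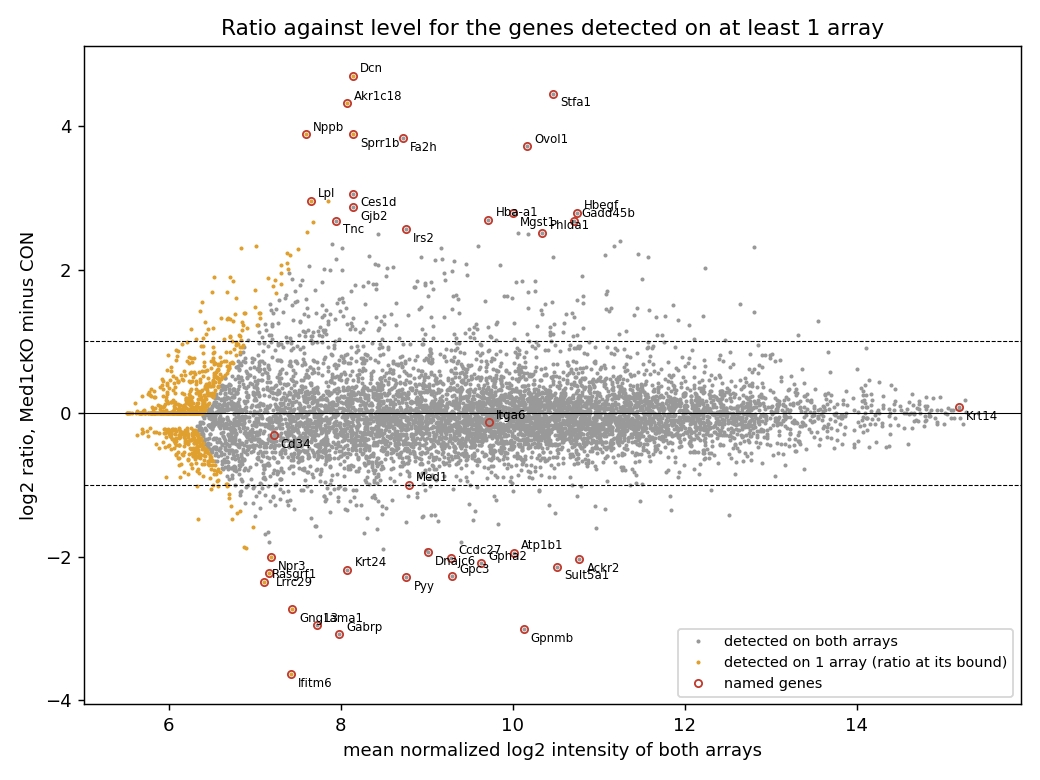
Each point is 1 of 7955 genes, with the mean normalized log2 intensity of both arrays on the x axis and the log2 ratio, Med1cKO minus CON, on the y axis; dashed lines mark 2-fold. Open red circles mark the always-named genes, the 12 highest, the 12 lowest and the 10 brightest genes detected on 1 array, and 314 genes lie at or above the upper line against 144 at or below the lower one.

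Stfa1, a cysteine protease inhibitor of the stefin A family, had the highest ratio among genes detected on both arrays and was 21.9-fold higher in the Med1cKO pool, with intensities of 465 in CON and 6846 in Med1cKO. Fa2h, which hydroxylates fatty acids for ceramides, was 14.2-fold higher, and Ovol1, a transcription factor of epithelial differentiation, 13.2-fold. Ces1d, a carboxylesterase, was 8.32-fold higher, Gjb2, the gap junction protein connexin 26, 7.32-fold, and the EGF receptor ligand Hbegf 6.90-fold. Mgst1, a glutathione transferase, was 6.89-fold higher, the alpha globin Hba-a1 6.46-fold, and the matrix protein tenascin C (Tnc) 6.42-fold. Gadd45b, a stress response gene, was 6.39-fold higher, the insulin receptor substrate Irs2 5.89-fold, and Phlda1 5.72-fold. These 12 ratios were 5.28 to 12.8 times the robust SD of genes of similar level. The genes were picked for the highest ratios, so large multiples follow from the choice. Without background correction Stfa1 was 14.5-fold higher, Fa2h 6.34-fold, Ovol1 8.98-fold, Ces1d 3.72-fold, Gjb2 3.45-fold, Tnc 3.00-fold and Irs2 3.53-fold. Gjb2, Mgst1 and Tnc each had another detected probe, with measured log2 ratios of 2.93, 2.99 and 3.29. Those of Gjb2 and Tnc were not detected in CON (intensities 180 and 219), so their ratios rest on a value near background. Stfa1, Hba-a1 and Ces1d have near-identical relatives that their probes could also bind, so which of these genes the values belong to is uncertain.

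Among genes detected in the Med1cKO pool only, the brightest was Dcn, the matrix proteoglycan decorin, at least 26.0-fold higher, with an intensity of 2297. Akr1c18, a steroid dehydrogenase, was at least 19.9-fold higher, and Sprr1b, a cornified envelope precursor, at least 14.8-fold. Nppb, the natriuretic peptide BNP, was at least 14.7-fold higher and lipoprotein lipase (Lpl) at least 7.78-fold. These bounds rest on the background correction, and without it they were 9.45-fold, 7.41-fold, 5.66-fold, 5.65-fold and 3.30-fold in the same order. Akr1c18 and Sprr1b also have close relatives.

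Gabrp, a GABA-A receptor subunit, had the lowest ratio among genes detected on both arrays and was 8.48-fold lower in the Med1cKO pool (log2 ratio -3.08), Gpnmb, a membrane glycoprotein, 8.08-fold, and Lama1, a laminin chain, 7.77-fold. Pyy, which encodes peptide YY, was 4.89-fold lower, the heparan sulfate proteoglycan Gpc3 4.83-fold, and the keratin Krt24 4.55-fold. Sult5a1 was 4.40-fold lower, Gpha2 4.26-fold, and Ackr2, a chemokine scavenging receptor, 4.09-fold. Ccdc27 was 4.05-fold lower, Atp1b1, a subunit of the sodium pump, 3.86-fold, and Dnajc6, a clathrin uncoating cofactor, 3.82-fold. These 12 ratios were 4.78 to 8.69 times the robust SD of similar genes, which again follows from the choice of the lowest ratios. Without background correction Gabrp was 3.57-fold lower, Gpnmb 5.98-fold, Lama1 3.13-fold, Pyy 3.11-fold and Krt24 2.54-fold. Second probes of Gabrp and Gpnmb had smaller measured log2 ratios of -1.91 and -1.62. Both were not detected in the Med1cKO pool, so these ratios rest on values near background. Genes detected in CON only included Ifitm6, at least 12.5-fold lower, Gng13, at least 6.65-fold, Rasgrf1, at least 5.10-fold, Lrrc29, at least 4.70-fold, and Npr3, at least 4.02-fold, or 4.52-fold, 2.74-fold, 2.26-fold, 2.14-fold and 1.93-fold without background correction.

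Of 32 fixed gene lists, 23 had at least 4 detected members. The medians of 13 lists lay in the highest 2.5% of matched random lists and none in the lowest, where 0.575 per tail would be met by chance if genes were independent. Genes of a list can differ together between 2 pools, and some lists share genes, so this number does not measure how unusual the count is. Of the 13, 3 are markers of other cell types, described last, and these were higher in the same pool as the keratinocyte lists.

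**Figure D2:**
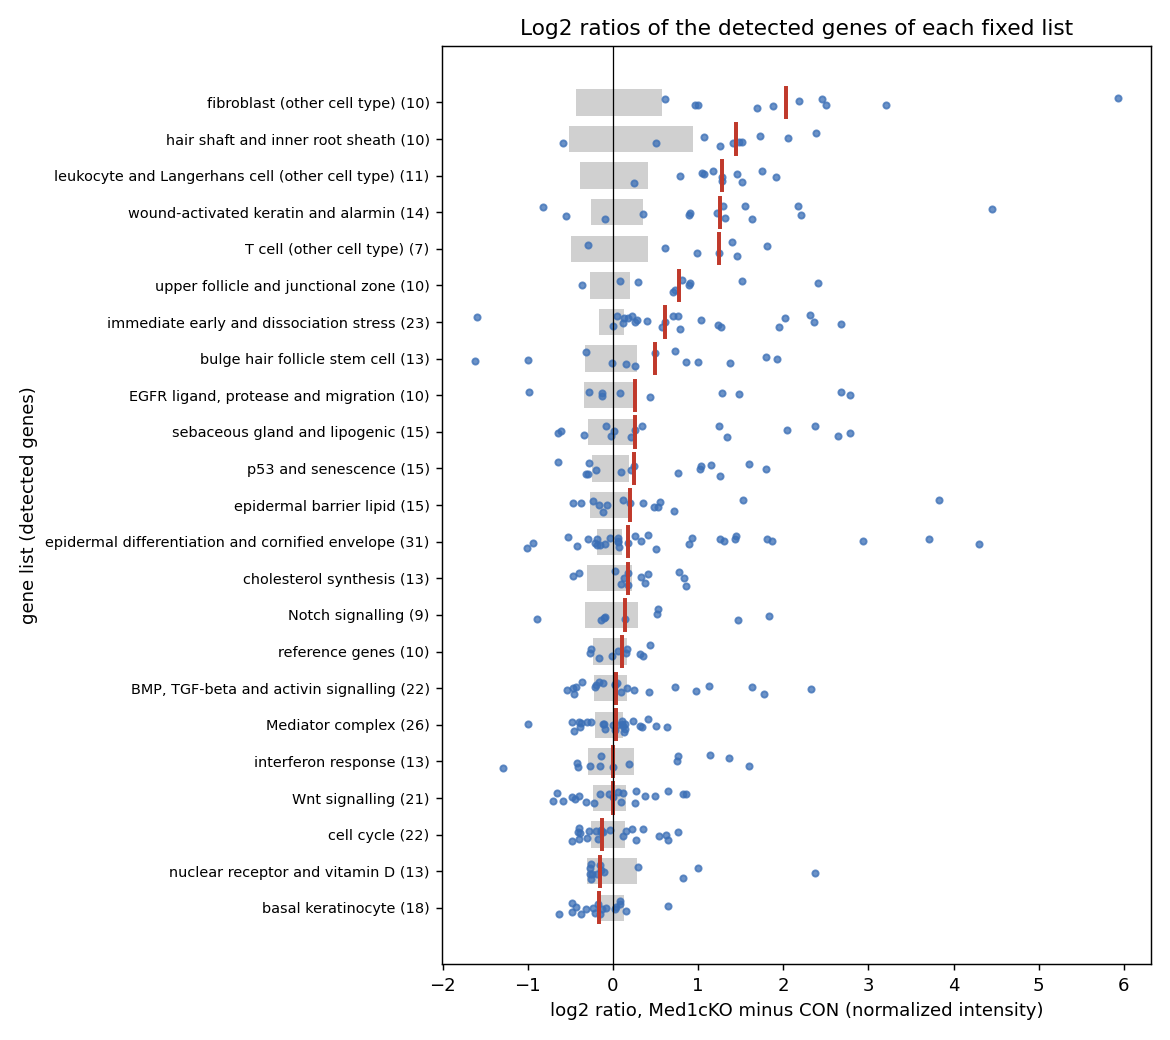
Points are detected genes of each list (number in brackets), placed by log2 ratio, Med1cKO minus CON, on the x axis; red bars are list medians and grey bands hold the central 95% of matched random lists. The 13 medians to the right of their band run from 0.18 (epidermal differentiation) to 2.03 (fibroblast markers), and the basal keratinocyte median of -0.16 is the lowest.

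Genes of epidermal differentiation and the cornified envelope stood apart as higher in the Med1cKO pool. Of 31 detected members, 9 were at least 2-fold higher and 1 at least 2-fold lower, and the median log2 ratio was 0.18 (percentile 99.9). Sprr1b and Ovol1 had the largest ratios. Tgm3, a transglutaminase that crosslinks the envelope, was at least 2.68-fold higher, and Lce1f, a late envelope protein, 3.65-fold (1.57-fold and 1.94-fold without background correction). The 9 also included Lce1b (2.71-fold), named after its value was seen. Further members were near 0 or lower, and 11 of the 31 were below 0. Chosen after their values were seen, Krt1, Krt10 and Lor, the abundant structural genes of the suprabasal layers, had log2 ratios of -0.21, 0.08 and 0.06, Flg2 -0.94, and Krt2, the member at least 2-fold lower, -1.004. Restricted to 29 members detected on both arrays, the median was 0.08 (percentile 95.1) and the list no longer stood apart.

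Barrier lipid genes had a median log2 ratio of 0.20 over 15 detected members (percentile 98.4), with 2 at least 2-fold higher and none lower. These were Fa2h and Alox12b, a lipoxygenase that oxidizes ceramide-bound lipid (2.89-fold, or 1.88-fold without background correction). Degs1, a ceramide desaturase, had log2 ratio 0.72 and Elovl4, a fatty acid elongase, 0.55. With cyclic loess the percentile was 97.3 and the list no longer stood apart.

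Basal keratinocyte genes did not stand apart. None of 18 detected members differed 2-fold, 12 were below 0, and the median log2 ratio was -0.16 (percentile 3.37). Krt5, the partner keratin of Krt14, had log2 ratio -0.48, Col7a1, the anchoring fibril collagen, -0.48, and Itgb1, the integrin beta1 chain, -0.63, although its other probe had 0.49. Sfn, the 14-3-3 sigma protein, went the other way at 0.64. Without background correction and with cyclic loess this list lay in the lowest 2.5%, at percentiles 1.55 and 0.91.

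Follicle-associated genes were higher as groups. In the upper follicle and junctional zone list, 9 of 10 detected members were above 0, 2 at least 2-fold, and the median log2 ratio was 0.77 (percentile 100). Plet1, a surface marker of this zone, was at least 4.61-fold higher (2.22-fold without background correction), Krt79, a keratin of the follicle canal, 2.86-fold, Krt17, 1.87-fold, and the transcription factor Gata6 1.85-fold. The bulge stem cell list had a median of 0.49 (percentile 99.8), with 9 of 13 members above 0, 2 at least 2-fold higher and 1 lower. Sox9, a follicle stem cell transcription factor, was 3.48-fold higher and Foxc1 2.60-fold, Lgr5 was at least 1.502-fold higher, and Angptl7 at least 1.66-fold lower. Ccn2, chosen after its value was seen, was the member at least 2-fold lower, with intensities of 3927 in CON and 1961 in Med1cKO. Without background correction Sox9 was 2.28-fold and Foxc1 1.94-fold higher and the bulge median was 0.31, and it still stood apart.

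Sebaceous and lipogenic genes had a median log2 ratio of 0.26 over 15 members (percentile 97.6), with 5 at least 2-fold higher and none lower. Besides Mgst1, Cidea, a lipid droplet protein, was at least 5.75-fold higher, the fatty acid binding protein Fabp5 at least 3.61-fold, and Pparg, a nuclear receptor of lipid storage, at least 1.99-fold, or 2.61-fold, 1.88-fold and 1.34-fold without background correction. This call was lost in 4 of 12 alternative settings. Hair shaft and inner root sheath genes had a median of 1.45 over 10 of 24 genes with a probe (percentile 99.95), and 1 was at least 2-fold higher, the transcription factor Dlx3 (3.32-fold). Krt71, Msx1 and Hoxc13 were at least 1.83-fold, 1.57-fold and 1.28-fold higher. Of the 10, 8 were detected in the Med1cKO pool only, close to background, and with such genes at their bound the median was 0.41 and the list still stood apart.

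Genes induced in wounded epidermis were also higher. In the list of wound keratins and alarmins, 11 of 14 detected members were above 0 but only 3 at least 2-fold higher, and the median log2 ratio was 1.25 (percentile 100). Of the 14, 7 were detected in the Med1cKO pool only. Besides Stfa1, Krt16, a keratin of wounded epidermis, was 4.64-fold higher, the neutrophil chemokine Cxcl1 4.51-fold, and the cytokine Il1b at least 1.90-fold. No member was 2-fold lower, but the alarmins Il33 and S100a8, chosen after their values were seen, had log2 ratios of -0.82 and -0.55. With genes detected on 1 array at their bound the median was 0.24, and the list still stood apart. The EGF receptor ligand, protease and migration list had a median of 0.26 over 10 members (percentile 97.7), with 4 at least 2-fold higher: Hbegf, Tnc, the ligand Epgn (2.43-fold), and vimentin (Vim, at least 2.62-fold, or 1.55-fold without background correction). Its call was lost in 5 of 12 alternative settings, with a median of 0.09 over genes detected on both arrays. In CON, Tnc and Vim were near background, with intensities of 251 and 234. Fibroblast markers were higher in the same pool, so the cells that these transcripts came from are not known.

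Immediate early and dissociation stress genes had a median log2 ratio of 0.61 over 23 members (percentile 100), with 21 above 0, 8 at least 2-fold higher and 1 at least 2-fold lower. Besides Gadd45b, Ier3 was 4.98-fold higher, Ier2 at least 4.86-fold (2.31-fold without background correction), and the heat shock gene Hspa1a, nearly identical to Hspa1b, 4.06-fold. Chosen after their values were seen, Fos, Egr1 and Atf3 had log2 ratios of 0.00, 0.05 and 0.11, at CON intensities of 25373, 29193 and 17962, and Klf2 was 3.03-fold lower. With genes detected on 1 array at their bound the median was 0.40, and the list still stood apart. In the p53 and senescence list 6 of 15 members were at least 2-fold higher and none lower, and the median was 0.25 (percentile 99.0). Pmaip1, a death-promoting BH3 protein, was 3.47-fold higher (2.296-fold without background correction), and Gadd45a and Sesn2, stress response genes, 2.40-fold and 2.22-fold (Sesn2 1.58-fold without it). Bbc3, another BH3 gene, was 3.03-fold higher by its brightest probe, while its other probes had measured log2 ratios of 0.46 (not detected in CON) and -0.07.

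**Figure D3:**
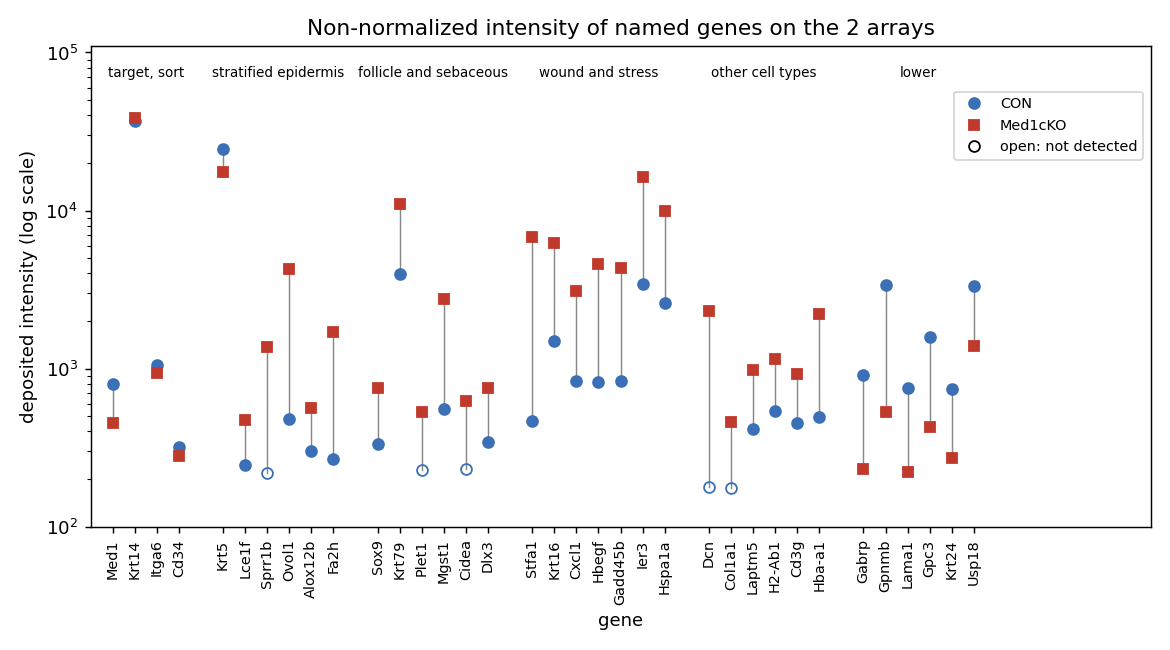
Deposited, non-normalized intensities of named genes (log scale) on the CON (blue circles) and Med1cKO (red squares) arrays; open symbols are not detected. Ier3 is at 3423 in CON and 16365 in Med1cKO, Dcn at 178 and 2297, and Gpnmb at 3393 and 530.5.

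Cell cycle genes did not stand apart: none of 22 detected members differed 2-fold, and the median log2 ratio was -0.13 (percentile 25.02), while the mean was 0.01. Of its members, Rrm2, Tpx2 and Pcna had log2 ratios of 0.65, 0.62 and 0.54, and Mcm7 was at least 1.42-fold higher. Wnt signalling genes had a median of 0.00 over 21 members (percentile 67.7), with none 2-fold different. The ligands Wnt3 and Wnt5a had -0.71 and -0.66, and the antagonist Wif1 and the receptor Fzd1 were at least 1.48-fold and 1.45-fold higher. The BMP, TGF-beta and activin list had a median of 0.04 over 22 members (percentile 76.4), but 4 were at least 2-fold higher and none lower. Id1, Id2 and Id3, targets of BMP signalling, were 5.02-fold, 3.42-fold and 3.09-fold higher and the activin subunit Inhbb 2.18-fold, although without background correction Id2 was 2.21-fold and Inhbb 1.56-fold higher. A second Id2 probe, not detected in CON, had a measured log2 ratio of 0.76. With the mean of 0.30 this list stood apart.

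In the Notch list the median was 0.14 over 9 members (percentile 85.8). The Notch target Hes1 was 2.76-fold higher, Hey1 at least 1.65-fold higher, and the ligands Jag1 and Jag2 had log2 ratios of 0.52 and -0.89. Of 2 detected Hedgehog genes, Smo had -0.40, with -0.29 and 0.14 by its other probes. Gli3 was detected in the Med1cKO pool only, with no fold to give. Nuclear receptor and vitamin D genes had a median of -0.15 over 13 members (percentile 18.4) and a mean of 0.20. None was at least 2-fold different by its brightest probe. Nr1d1 had log2 ratio 0.99, and 1.19 by a second probe. The vitamin D receptor Vdr had 0.29, with 0.28 and -0.17 by its other probes, and Esr1 was at least 1.05-fold higher.

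The other Mediator subunits were close to 0. Over 26 detected genes of the complex the median was 0.04 (percentile 83.2), none differed 2-fold, and after Med1 the largest ratios were those of Med16 (0.63), Med7 (0.51) and Med20 (-0.48). Cholesterol synthesis genes had a median of 0.18, with 11 of 13 above 0 (percentile 95.8). Dhcr7, Msmo1 and Insig1 had 0.86, 0.84 and 0.77, and Sc5d -0.47. Among genes detected on both arrays this list stood apart (percentile 97.9). Interferon response genes had a median of 0.00 over 13 members (percentile 60.4) and went both ways. Oasl2 and Isg15 were 3.03-fold and 2.196-fold higher (1.73-fold and 1.54-fold without background correction), Ddx58, the RNA sensor RIG-I, at least 1.25-fold higher, and Usp18, a brake on interferon signalling, 2.44-fold lower, with log2 ratios of -1.18 and -1.03 by its other probes. Reference genes had a median of 0.11 over 10 members (percentile 91.9), with none 2-fold different. Tfrc, Gapdh and Tbp had 0.44, 0.35 and -0.27, and the probes of Actb ranged from 0.99 to -0.84, with 0.31 for the brightest.

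Markers of other skin cell types were higher in the Med1cKO pool, in parallel with the keratinocyte, follicle, wound and stress lists above. All 10 detected fibroblast genes were above 0, 5 at least 2-fold, with a median log2 ratio of 2.03 (percentile 100), or 0.90 with genes detected on 1 array at their bound. Besides Dcn, the collagen Col1a1 was at least 3.74-fold higher, Serping1 at least 2.41-fold, and Lum at least 1.75-fold. All 11 detected leukocyte and Langerhans cell genes were above 0, 8 at least 2-fold, with a median of 1.28 (percentile 100). Laptm5 was 3.38-fold higher, Cd207, the Langerhans cell lectin, 2.87-fold, the MHC class II gene H2-Ab1 2.74-fold, and Lyz2 at least 1.18-fold. Other probes had smaller measured log2 ratios, of 0.77 for Cd207 and of 0.82, 1.24 and 1.04 for H2-Ab1. Of 7 detected T cell genes 6 were above 0 and 4 at least 2-fold higher, with a median of 1.24 (percentile 99.99). Among the T cell receptor complex genes, Cd3e was at least 3.49-fold higher, Cd3g 2.74-fold and Cd3d 2.37-fold, and Nkg7 was 2.63-fold higher. Without background correction Col1a1 was 1.93-fold higher, Serping1 1.48-fold, Cd207 1.64-fold, Cd3e 1.84-fold, Cd3d 1.48-fold and Nkg7 1.58-fold, and the medians of the 3 lists were 0.89, 0.70 and 0.60. Leaving out the genes of all lists of other cell types, a step chosen after seeing the data, left 295 genes at least 2-fold higher and 144 lower. This step kept 7918 of 7955 genes, and any other transcripts of such cells stayed in. The count therefore cannot show how much such cells add to the excess of higher genes.

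The remaining lists had fewer than 4 detected genes. Of the endothelial genes, Esam was at least 1.26-fold and Egfl7 at least 1.21-fold higher, and Robo4 had log2 ratio 0.01. Another Egfl7 probe, detected in CON only, had a measured log2 ratio of -0.72. The melanocyte gene Dct was detected in the Med1cKO pool only, with no fold to give. Of the muscle genes, Mylpf was at least 1.32-fold higher, and Tnni2 and Eno3 had 0.61 and -0.14. Lpl was the detected adipocyte gene and Hba-a1 the detected erythroid gene. The Merkel cell list had Tubb3 at -0.67, and none of 8 mast cell genes was detected. Xist, transcribed from the inactive X chromosome of females, had intensities of 7497 in CON and 5364 in Med1cKO (log2 ratio -0.49, and -0.02 by a second probe), and 3 Y-linked probes were detected on neither array.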

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

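No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out and no slide fitted as a block. Signal over background limits dim genes: the robust SD of ratios was 0.97 in the dimmest of 10 level bins and 0.23 in the brightest. The excess of higher over lower genes held in all alternatives, with 52.8% to 80.5% of the counted genes higher. Of the 13 lists that stood apart, 9 did so under every alternative that gave a value, and those lost were epidermal differentiation, barrier lipid, sebaceous and EGF receptor lists; fibroblast and hair shaft lists had too few genes detected on both arrays for a value. Of 1261 values of named genes under the alternatives, 1137 moved less than the spread of genes of similar level, 124 moved more, and 3 of all these values, with genes detected on 1 array at their bound, had another sign than reported (Egfl7 with offset 1 and, like Actb, with the mean over probes). Changes of the filter alone cannot move a gene detected on both arrays, so part of the 1137 is fixed by construction. Of 130 named genes, 47 moved more without background correction and 45 with the authors' values. Where not given by the construction of the setting, the cause was not tested.

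Counts of genes at least 2-fold higher and lower were 145 and 43 without background correction, 163 and 46 with the authors' values, and 483 and 254 with no filter. They were 736 and 659 at 1.5-fold and 120 and 29 at 3-fold. With offset 50, 95 were lower.

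List medians (log2) that moved by more than the spread of matched random lists are as follows. Without background correction they were 0.31 (bulge), 0.64 (upper follicle), 0.47 (hair shaft), 0.41 (wound), 0.39 (immediate early), 0.89 (fibroblast), 0.70 (leukocyte) and 0.60 (T cell). The authors' values gave 0.65 (upper follicle), 0.57 (hair shaft), 0.48 (wound), 0.35 (immediate early), 0.98 (fibroblast), 0.78 (leukocyte) and 0.64 (T cell). A median shift gave 0.27 for epidermal differentiation. Offset 50 gave 0.97 (hair shaft), 0.83 (wound), 0.53 (immediate early), 1.37 (fibroblast) and 0.99 (T cell), and offset 1 gave 1.81 (hair shaft), 1.72 (wound) and 2.58 (fibroblast). Smaller values with a larger offset follow from its construction, since it is added to both arrays.

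With detection p below 0.05 the medians were 0.36 (barrier lipid) and 0.45 (EGF receptor). Genes detected on both arrays gave 0.077 (epidermal differentiation), 0.90 (wound), 0.087 (EGF receptor), 0.48 (immediate early) and -0.14 (interferon). No filter gave 0.093 (epidermal differentiation), 0.24 (bulge), 0.24 (hair shaft), 0.46 (wound), 0.093 (EGF receptor), 0.42 (p53), 0.98 (fibroblast), 1.06 (leukocyte) and 0.61 (T cell). The mean over probes gave 0.26 (epidermal differentiation), 0.57 (EGF receptor), 0.13 (Wnt), 0.70 (immediate early) and 0.42 (p53). Genes at their bound gave 0.41 (hair shaft), 0.24 (wound), 0.40 (immediate early) and 0.90 (fibroblast).

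The mean in place of the median gave 0.64 (epidermal differentiation), 0.46 (barrier lipid), 0.77 (sebaceous), 0.72 (EGF receptor), 0.01 (cell cycle), 0.30 (BMP, TGF-beta and activin), 0.36 (Notch), 0.20 (nuclear receptor), 0.80 (immediate early), 0.24 (interferon) and 0.50 (p53).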

Other observations

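The tests of the patterns on other cell types and on immediate early genes were chosen only after the results were seen, while those on the Zfp genes were written before their results. Genes of the families below were named after their values were seen.

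Grouping detected genes by the letters of their symbol gave 189 families of at least 6 genes. The medians of 15 families lay in the highest 2.5% of matched random lists and those of 7 in the lowest, with 4.725 per tail by chance if genes were independent. The late cornified envelope (Lce) genes led the higher families, with a median log2 ratio of 1.71, and 5 of 6 were at least 2-fold higher in the Med1cKO pool. Lce1a2 was 3.58-fold higher, Lce1d 3.46-fold, Lce1c 3.11-fold and Lce1b 2.71-fold, while Lce1m, with an intensity of 5014 in CON, had log2 ratio -0.03. The Lce genes are close relatives, so their probes are not independent. Chemokines of the Cxcl family had a median of 1.25, which includes Cxcl9 and Cxcl10, detected in the Med1cKO pool only and close to background. The median was 0.81 over the 4 genes detected on both arrays, 0.50 without background correction and 0.58 with the authors' values. Cxcl16 was 2.14-fold higher, whereas Cxcl14, with a CON intensity of 13982, had -0.78. Of 10 Klf transcription factors 3 were at least 2-fold higher, namely Klf13 (2.98-fold), Klf7 (2.14-fold) and Klf16 (2.11-fold), against 1 lower, Klf2, with a family median of 0.56. The Pdlim genes, which bind the actin cytoskeleton, had a median of 0.75, with Pdlim7 5.13-fold and Pdlim3 3.98-fold higher. The single folds are after background correction, and without it the medians of the Lce, Klf and Pdlim genes were 1.20, 0.54 and 0.53. All 4 families stayed in the highest 2.5% under the 10 settings of background, scaling, filter and probe choice. A detection p below 0.05 and no filter kept the same family members, so only detection on both arrays tested the filter.

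Wnt ligands were lower as a family, although the fixed Wnt signalling list, which also holds receptors, antagonists and targets, had a median of 0.00. Of 10 detected Wnt genes 8 had log2 ratios below 0, with a median of -0.48 and a range of -0.52 to -0.26 over the 10 settings. Wnt6 was 2.33-fold lower, and Wnt3a and Wnt16 had -0.59 and -0.52, while Wnt10a had 0.27. The Man (mannosidase) genes lay in the lowest 2.5% in all 10 settings, with medians of -0.52 to -0.37. DNA repair genes of the Rad group had a median of -0.60, with 10 of 11 below 0 and none at least 2-fold different. Rad52, Rad54b and Rad9a had -0.62, -0.61 and -0.60. The Rad genes left the lowest 2.5% in 3 of the 10 settings. The median was -0.20 at percentile 22.5 over the 8 genes detected on both arrays, -0.23 at 10.8 with the mean over probes, and -0.21 at 3.3 without background correction.

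Fibroblast, leukocyte and T cell markers were all higher in the Med1cKO pool, which bears on how far the other differences belong to keratinocytes. Array processing is not the whole cause: over all alternatives that gave a value, the 3 list medians never lay below percentile 99.95, although without background correction they were 0.89, 0.70 and 0.60. Of the detected leukocyte and T cell markers, 9 of 11 and 5 of 7 were detected in CON too. The alpha globin Hba-a1, an erythroid marker, read 492 in CON and 2231 in Med1cKO. By their use as markers, these values go with some RNA of other cells in both pools. Why the markers were higher in Med1cKO stays open. More RNA of other cells and expression of these genes by Med1-deficient keratinocytes cannot be told apart with 1 pool per genotype. Of 27 detected markers 26 were higher (all but Il2rb), but only 16 of the 27 were detected in CON. The rest entered through the Med1cKO array and were almost bound to be higher there, so this count decides little. Among markers detected on both arrays, the leukocyte and T cell medians were 1.28 and 1.24. How many other cells the gate for integrin alpha6 removed is not given in the sources used here. Among genes abundant in fibroblasts, Dcn reached 2297 in the Med1cKO pool, Col1a1 456 and Col3a1 239.9, while Col1a2, like the pan-leukocyte gene Ptprc, was among 17 markers detected on neither array, and no table gives the level these probes reach in pure cells. The prediction for RNA of other cells asked for Col1a2 and Ptprc to be detected, so this part of it was not met. More such cells in the skin of these 3 mice also stays open, untested with 1 pool per genotype.

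Immediate early and stress genes were higher in the Med1cKO pool under every alternative, above all 10000 random lists (percentile 100), which argues against array processing as the whole cause, although the median was 0.39 without background correction and 0.35 with the authors' values, against 0.61. Longer or harsher handling of these cells before lysis would be expected to raise the early response genes Fos, Fosb, Jun, Junb, Egr1, Atf3, Dusp1 and Zfp36, whose median log2 ratio was 0.20, but other immediate early genes were higher, such as Ier3 (2.32), Fosl1 (1.95), Myc (1.27) and Egr2 (1.23). The choice of these 8 genes thus decides nothing, and they already had a median intensity of 21668 in CON, where the brightest probe of the array read 44136, so a further difference may be compressed. Handling and genotype cannot be told apart with 1 sort per genotype, and an effect of Med1 loss on these genes is an untested hypothesis.

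Zinc finger (Zfp) genes were lower in the Med1cKO pool as a family, with a median log2 ratio of -0.30 over 146 genes, 39 of them above 0. Under the 10 settings the median ran from -0.32 to -0.18 and its percentile was never above 0. This argues against background correction or scaling as the whole cause. A detection p below 0.05 and no filter kept the same 146 genes and median, so these settings could not test the filter. Over the 133 genes detected on both arrays the median was -0.29. Most Zfp probes are dim: in the brighter 50% of detected genes, 39 Zfp genes had a median of -0.13 at percentile 6.62, and the 107 dimmer ones -0.40. The test leaves open whether probes near background carry part of the difference. The percentile of the brighter genes lay neither in the lowest 2.5%, as predicted without this cause, nor near the middle of the random lists. Even a percentile in the lowest 2.5% could not have excluded a part carried by dimmer probes. The cut was at the middle level of detected genes, so the 107 dimmer ones are not all near background. A lower level of Zfp transcripts after Med1 loss may be considered, as an untested hypothesis.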
